A study of Mus musculus with 18 samples.

How the data were processed

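RNA was measured by sequencing in CD8+ and CD4+ T cells that had been flow sorted from B16f10-OVA tumors, a mouse melanoma line that carries ovalbumin. Per the labels, the mice carried a floxed miR-155 gene either without Cre ("floxed" here) or with Cre under the CD4 promoter, which is active in the T cell lineage ("deficient" here). Some of the deficient mice had received antibodies against PD-1/PD-L1 and CTLA-4 (the "blockade" here), per the labels' protocols. The 18 libraries make 6 groups of 3, and each library pools cells of 2 to 3 tumors, per the series' design text. Floxed mice with blockade were not analysed here, so the antibody effect was measured in deficient cells alone.

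The deposited values are counts of reads per gene, 1 file per library. Per the file headers, they were made with featureCounts 1.5.1 with the strand option at 2 (reverse stranded) and the Ensembl release 87 annotation. Per the submitters' processing notes, the genome build was GRCm38, and STAR, featureCounts and DESeq2 were used, with no version given there. The files hold 49671 gene models. Of these, 49326 IDs were found in the reference annotation (GENCODE M21), which gave their symbols, and 91.4% had the same start and end in both. Coordinates are those of the files. The counts were used as deposited, with no row left out of the totals. Total counts ran from 3.2 to 11.65 M (mega) per library, and 15165 to 19533 genes had at least 1 count. A floor of 3 counts corresponds to 0.258 to 1.242 CPM (counts per M counts, on the TMM scale of the CPM values given), depending on the library. The floor covers counting error only. Fold values against a group with no count use 3 counts over the whole group.

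All 18 libraries entered 1 fit with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM scaling, robust quasi-likelihood fit), which left 12 residual degrees of freedom and tested 14080 genes. The common biological coefficient of variation was 0.229. Adjusted p-values are Benjamini-Hochberg values from edgeR's quasi-likelihood test, and a gene was called at an adjusted p under 0.05. The comparisons were deficient against floxed ("deletion"), deficient with against without antibodies ("blockade"), and treated deficient against untreated floxed cells, each within CD8 and within CD4 cells. A further 3 contrasts were the differences of the deletion effect and of the blockade effect between CD8 and CD4 cells, and CD8 against CD4 cells of floxed mice. Group values are TMM-scaled CPM, as mean ± SD over 3 libraries. Log2 fold changes carry the standard error (SE) of the fit. The p-values measure only the spread between libraries, which are pools, and the labels do not say whether pools of different groups or cell types share animals.

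The gene lists, the rule for named genes, the tests and most alternatives were fixed before the data were examined. Named are Mir155hg, Mir155, Cd4, Cd8a and Cd8b1. Further named are, per comparison, up to 10 genes with the largest rise and 10 with the largest fall among called genes with a group mean of at least 5 CPM and libraries that do not overlap between the groups (this last condition was dropped for the differences between cell types). Also named are list members with the smallest adjusted p, and Socs1, Inpp5d, Ifng, Gzmb, Prf1, Pdcd1, Ctla4, Havcr2, Tcf7 and Foxp3 whatever their result. The rule allowed 4 members per list, and the text keeps to the 2 with the smallest adjusted p, in the deletion and blockade comparisons. Unnamed gene models and receptor segments were counted but not named. The groups did not overlap for 34.2% of tested genes in the CD8 deletion, 28.0% in the CD4 deletion, 44.1% in the CD8 blockade and 20.0% in the CD4 blockade, where chance gives 10% for 3 against 3.

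The 35 lists were CD8 lineage, CD4 lineage, pan T cell, miR-155 targets from the literature, cytotoxic effector, inhibitory receptors and exhaustion, naive and memory, type I interferon response, interferon gamma response, cell cycle G1 to S, cell cycle G2 and mitosis, regulatory T cell, Th1, Th2, Th17, T follicular helper, T cell receptor induced activation, STAT5 and cytokine signalling feedback, glycolysis, oxidative phosphorylation, cholesterol synthesis, hypoxia response, chemokines and homing receptors, and dissociation stress, and markers of melanoma cells, macrophages and monocytes, dendritic cells and antigen presentation, neutrophils, B and plasma cells, natural killer cells, fibroblasts, endothelial cells, erythroid cells, gamma delta T cells, and male and female transcripts. Some genes stand in more than 1 list. Lists were tested with camera (preset correlation of 0.01, Benjamini-Hochberg over the 35 lists of a comparison), and again with camera's estimated correlation and with fry from limma 3.58.1. Camera compares a list with the other genes, while fry tests whether the members move on balance one way. Per list, the text gives the members called over all genes and those adjusted over the list alone.

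The miR-155-5p seed test used the longest annotated 3' UTR of each gene. Genes with a 7mer-m8 or 8mer seed match were compared with the others by camera. The difference of medians was set beside that of 353 control 7mers of the same base composition. With 3' UTR length matched, the difference of means within bins of length was used in its place. The relation between deletion and blockade effects was set beside 20 simulations with no effect, because both comparisons share the untreated deficient libraries. The steps were tested on simulated data drawn from gene means over all 18 libraries and their depths, with changes placed in the deficient CD8 group alone (13713 genes). There, 49 of 96 genes changed 2-fold (51%) and 81 of 100 changed 4-fold (81%) were recovered. Another 8 unchanged genes were called, 5.8% of calls, and camera called 0 of 20 unchanged sets (unadjusted p, threshold 0.05) while edgeR's quasi-likelihood test called 0 genes in a comparison with no change.

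Alternatives were RLE scaling, no low-count filter, a stricter filter, DESeq2 1.42.0, limma voom with quality weights, a fit of 1 cell type alone, the replicate number as a block, and leaving out each library in turn. For the seed test they were 8mer sites alone, all annotated 3' UTRs and genes above the median expression, the last also for the relation of deletion and blockade. A further 2 were added after the data had been seen. They are the levels of melanoma and macrophage markers as covariates, and leaving out the 3 libraries in which over 5% of the counts fell on ribosomal-like gene models. Each level is the mean log CPM of that marker list, so with the covariates the melanoma and macrophage lists lose their change by construction. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. Reads, isoforms and mature microRNAs were not analysed here. Results for some single genes are not reported here.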

Results

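Transcripts were counted in CD8+ and CD4+ T cells sorted from B16f10-OVA melanomas that had grown for 12 days. For each cell type there were 3 libraries of floxed mice, 3 of mice with miR-155 deleted in T cells (deficient) and 3 of deficient mice given antibodies against PD-1/PD-L1 and CTLA-4 on days 3, 6 and 9 of growth. The stated doses were 250 ul at 1, 1 and 0.4 mg/ml, and it was not clear whether these are per antibody or per day. MiR-155 is a microRNA that activated T cells make in large amounts. PD-1 and CTLA-4 are receptors that restrain T cells. The libraries of CD8 cells held 5.11 to 9.79 M counts (M, mega) in the floxed group (mean 7.39), 5.72 to 7.63 in the deficient group (mean 6.82) and 3.2 to 11.65 in the treated group (mean 7.98). Those of CD4 cells held 4.47 to 7.39 M (mean 6.07), 3.87 to 7.38 (mean 6.14) and 3.36 to 11.4 (mean 8.34). In 3 libraries over 5% of counts fell on ribosomal-like models, namely floxed CD8 replicate 1 (5.82%), treated CD8 replicate 2 (25.6%) and deficient CD4 replicate 3 (11.8%).

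The target of the deletion was low in every deficient library. Mir155hg, the host transcript of miR-155 (ENSMUSG00000097418, GRCm38 chromosome 16, 84703167 to 84715245, plus strand), stood at 16.3 ± 6.26 CPM in floxed CD8 cells, 1.01 ± 0.84 in deficient and 0.428 ± 0.0907 in treated deficient CD8 cells (SD, n = 3 each). In CD4 cells the levels were 6.61 ± 1.68, 0.405 ± 0.353 and 0.0928 ± 0.0957 CPM. Raw counts were 144, 196 and 51 in the floxed CD8 libraries, 2, 7 and 12 in the deficient and 4, 1 and 5 in the treated ones. In CD4 cells they were 29, 60 and 27, then 5, 0 and 2, then 1, 0 and 2, where a count of 0 allows up to 3. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the log2 fold change of Mir155hg was -4.04 ± 0.65 (SE, adjusted p = 0.000205) in CD8 and -4.05 ± 0.74 (adjusted p = 0.00126) in CD4 cells. The separate model of the miR-155 precursor (ENSMUSG00000065397) had 0 counts in all 18 libraries, so mature miR-155 was not measured.

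**Figure D1:**
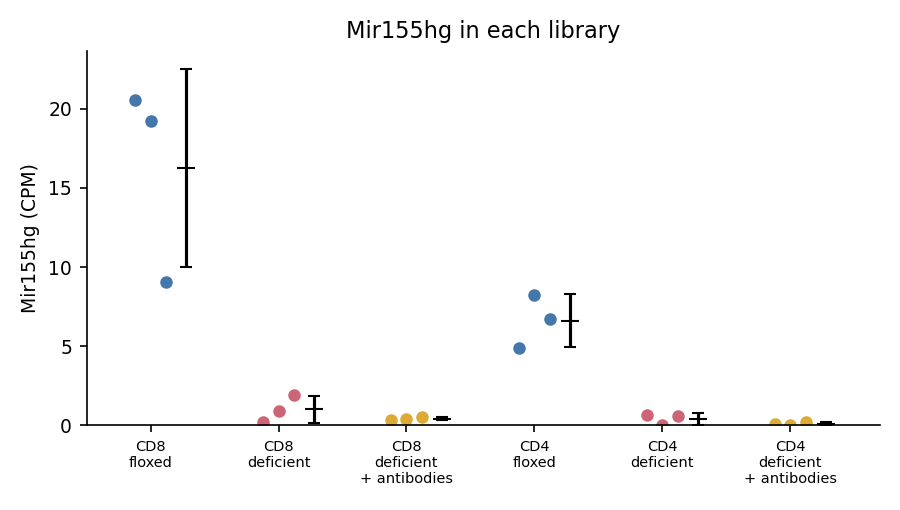
Mir155hg in each library, in CPM, by cell type and group. Points are libraries and bars show the mean and SD of 3 libraries. The floxed libraries lay above all deficient libraries of the same cell type.

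Lineage transcripts matched the sort for the most part. Cd4, the co-receptor of helper T cells, was at 1.54 ± 1.57, 1.44 ± 0.814 and 1.83 ± 0.511 CPM in floxed, deficient and treated CD8 cells and at 379 ± 128, 603 ± 62.8 and 954 ± 148 CPM in the CD4 groups (SD, n = 3 each). Cd8a, the co-receptor of cytotoxic T cells, was at 1300 ± 153, 681 ± 52.6 and 1040 ± 110 CPM in CD8 cells. Floxed CD4 cells also held Cd8a, at 102 ± 75.8 CPM (14.6 to 150 in single libraries), against 0.226 ± 0.0789 in deficient and 8.09 ± 8.27 in treated CD4 cells. Cd8b1, the partner chain, followed, at 656 ± 85.0, 388 ± 43.7 and 586 ± 60.7 CPM in CD8 and 65.7 ± 42.3, 10.8 ± 5.77 and 17.4 ± 9.98 CPM in CD4 cells. Between floxed CD8 and CD4 cells, edgeR's quasi-likelihood test called 2662 genes higher in CD8 and 2844 higher in CD4 cells of 14080 tested.

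The first question was what loss of miR-155 does in tumor CD8 T cells. Deficient CD8 cells held more transcripts of naive and memory T cells and fewer of effector function, inhibitory receptors and the cell cycle. S1pr1, which guides lymphocytes out of tissue, rose from 44.1 to 291 CPM (log2 fold change 2.72 ± 0.29). Of 18 naive and memory genes 13 rose and 0 fell (16 and 0 adjusted over the list alone), with a median log2 fold change of 1.44 (camera adjusted p = 1.6e-16). Of 25 cytotoxic effector genes 1 rose and 16 fell (1 and 19 adjusted over the list alone, median -1.09, camera adjusted p = 1.52e-13). Gzmb, a granule protease, went from 2560 ± 229 to 754 ± 330 CPM (-1.76 ± 0.25). Prf1, which forms pores in target cells, went from 1330 ± 233 to 325 ± 158 CPM (-2.03 ± 0.43). Nkg7 and the chemokine Ccl4 fell by 1.14 and 1.92 on the log2 scale. Of 23 inhibitory receptor and exhaustion genes 4 rose and 14 fell (5 and 17 adjusted over the list alone, median -1.30, camera adjusted p = 2.49e-11). Havcr2 (TIM-3) changed by -2.68 ± 0.28, Entpd1 (the ectonucleotidase CD39) by -2.29 ± 0.18, Pdcd1 (PD-1) by -1.68 ± 0.15 and Ctla4 by -1.30 ± 0.18. These 3 lists were the ones also called with an estimated correlation, each at an adjusted p = 0.0488.

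Proliferation genes were lower as well. All but 1 of 28 genes of G2 and mitosis fell (27 fell, 28 adjusted over the list alone, median -0.92), and Mki67, a marker of cycling cells, went from 1330 to 504 CPM (-1.40 ± 0.20). Camera gave the list an adjusted p = 5.95e-20, and an adjusted p = 0.0732 with an estimated correlation. Of 27 genes of G1 to S, 22 fell and 0 rose (23 and 0 adjusted over the list alone, median -0.79), among them the replication genes Mcm3 (-0.84 ± 0.12) and Pole (-1.12 ± 0.16). That list had a camera adjusted p = 1.13e-16, and an adjusted p = 0.0521 with an estimated correlation. Th1 genes fell, 10 of 16 with 1 rise (12 and 2 adjusted over the list alone, median -0.95, camera adjusted p = 1.17e-05, adjusted p = 0.0732 with an estimated correlation). Their leading members were the homing receptor Cxcr6 (-1.67 ± 0.18) and the transcription factor Bhlhe40 (-1.58 ± 0.26). Regulatory T cell genes, led by Entpd1 and Nrp1, fell in 11 and rose in 1 of 23 cases (14 and 2 adjusted over the list alone, median -0.85, camera adjusted p = 3e-07, adjusted p = 0.0521 with an estimated correlation). Genes induced by the T cell receptor fell in 8 and rose in 1 of 24 cases (13 and 1 adjusted over the list alone, median -0.66, camera adjusted p = 0.000277, adjusted p = 0.21 with an estimated correlation), with Irf8 and the co-stimulatory receptor Tnfrsf9 in front. Follicular helper genes rose in 5 and fell in 1 of 9 cases (6 and 1 adjusted over the list alone, median 1.04, camera adjusted p = 0.000295, adjusted p = 0.0521 with an estimated correlation), among them Slamf6 and Maf.

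Reported targets of miR-155 and interferon response genes were higher. Of 30 targets from the literature 9 rose and 0 fell (9 and 0 adjusted over the list alone), with a median of 0.14 (camera adjusted p = 0.000415, adjusted p = 0.0732 with an estimated correlation). Maf rose by 1.51 ± 0.19, Ifngr1, a chain of the interferon gamma receptor, by 1.08 ± 0.14 and Socs1, a brake on cytokine signalling, from 24.4 to 49.1 CPM (1.01 ± 0.15). Inpp5d, an inositol phosphatase and a known target, stood at 203 ± 63.0 and 192 ± 14.5 CPM (-0.08 ± 0.15, edgeR quasi-likelihood adjusted p = 0.77). Of 32 type I interferon response genes 15 rose and 0 fell (15 and 0 adjusted over the list alone, median 0.66, camera adjusted p = 9.33e-08, adjusted p = 0.263 with an estimated correlation). Of 35 interferon gamma response genes 18 rose and 2 fell (18 and 5 adjusted over the list alone, median 0.47, camera adjusted p = 5.8e-08, adjusted p = 0.21 with an estimated correlation). Irf7 rose by 1.23 ± 0.20, Tgtp1 by 2.42 ± 0.25 and Socs3 by 2.16 ± 0.22. Over all genes with a 3' UTR, 1143 of 12102 held a miR-155 seed site. Their median log2 fold change was 0.09 against -0.02 for the others, a difference of 0.108 that none of 353 control 7mers reached. With 3' UTR length matched, the difference of means was 0.102, and 29 of 353 controls were as large. Camera gave a p of 0.0386 for the seed set, which was 0.0868 with an estimated correlation and 0.0829 for 8mer sites alone. The p rose to 0.0885, 0.103, 0.0597 and 0.0727 without floxed CD8 replicate 2 or 3 or deficient CD8 replicate 1 or 3.

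Smaller lists moved as follows. CD8 lineage genes fell in 2 of 6 cases (2 adjusted over the list alone, median -0.85, camera adjusted p = 0.00897, adjusted p = 0.173 with an estimated correlation). Pan T cell genes such as Thy1 and Cd28 fell in 5 of 12 (6 adjusted over the list alone, median -0.32, camera adjusted p = 0.00259, adjusted p = 0.342 with an estimated correlation). Cholesterol synthesis genes fell in 5 and rose in 1 of 20 cases (6 and 1 adjusted over the list alone, median -0.28, camera adjusted p = 0.0289, adjusted p = 0.378 with an estimated correlation). The camera adjusted p of that list rose to 0.0595 without deficient CD8 replicate 1 and to 0.0503 without replicate 3. Hypoxia response genes, among them Pdk1 and Vegfa, rose in 8 of 19 cases (8 up and 1 down adjusted over the list alone, median 0.07, camera adjusted p = 0.024, adjusted p = 0.427 with an estimated correlation, and 0.0545 with the preset correlation without deficient CD8 replicate 2). Lists without a camera call were CD4 lineage (0 of 5 genes called, median -0.51), Th2 (1 up and 2 down of 8, median 0.11), Th17 (1 up of 7, median 0.72) and STAT5 and cytokine feedback (6 up and 4 down of 22, median 0.04). So were glycolysis (1 up and 4 down of 21, median -0.17), oxidative phosphorylation (1 down of 28, median -0.05) and chemokines and homing receptors (9 up and 8 down of 28, median 0.36). The last were dissociation stress (4 up and 2 down of 20, median 0.12), neutrophils (1 up and 1 down of 6, median 0.94) and male and female transcripts (0 of 4, median 0.02). With the melanoma and macrophage marker levels as covariates, calls of the CD8 deletion were lost for CD8 lineage (median 0.491), pan T cell (-0.146), T cell receptor induced (-0.091) and hypoxia genes (0.053). The Th1 (-0.461), type I interferon (0.397), cytotoxic effector (-0.51), exhaustion (-0.996), G1 to S (-0.526) and G2 and mitosis lists (-0.873) kept their calls with smaller medians. The naive and memory list kept its call with a larger one (1.749).

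Markers of other cells moved with the deletion in CD8 cells. Melanoma transcripts, led by Sox10 and Gpnmb, summed to 181.8 ± 23.08 CPM in floxed, 2651 ± 1046 in deficient and 887 ± 776.7 in treated CD8 cells (SD, n = 3 each). In the deletion 13 of 15 rose (14 adjusted over the list alone, median 3.76, camera adjusted p = 1.91e-08, adjusted p = 0.183 with an estimated correlation). Macrophage and monocyte genes such as Itgam and Ctss rose in 8 of 20 cases (12 adjusted over the list alone, median 1.12, camera adjusted p = 6.78e-08, adjusted p = 0.201 with an estimated correlation). The antigen presentation genes H2-Ab1 and H2-Aa led the dendritic cell list, where 7 of 14 rose (9 adjusted over the list alone, median 1.71, camera adjusted p = 1.62e-05, adjusted p = 0.142 with an estimated correlation). Also called higher by camera were natural killer cell genes (3 up and 1 down of 11, 5 and 1 adjusted over the list alone, median 1.15, adjusted p = 0.00653) and B and plasma cell genes (2 of 7, 3 adjusted over the list alone, median 1.62, adjusted p = 0.000783). So were gamma delta T cell genes (3 of 4, 3 adjusted over the list alone, median 2.03, adjusted p = 0.0175). With an estimated correlation these 3 lists had an adjusted p = 0.0521, an adjusted p = 0.0521 and an adjusted p = 0.183. Fibroblast genes (2 of 7 up, 2 adjusted over the list alone, median 4.49, or 3.71 with groups at 0 set to the floor), erythroid genes (2 of 3 up, 3 adjusted over the list alone, median 5.98, or 3.397 at the floor) and endothelial genes (1 of 4 up, 1 adjusted over the list alone, median 0.52) had a camera adjusted p = 0.0175, 0.0175 and 0.0399. These became an adjusted p = 0.264, 0.201 and 0.21 with an estimated correlation, and the endothelial call was lost without floxed CD8 replicate 2 (0.0926) or deficient CD8 replicate 2 (0.0912). With the covariates the calls of the endothelial (median -0.272) and erythroid lists (4.029) were lost. Those of the melanoma (0.182) and macrophage lists (-0.281) were lost too, but these lists make up the covariates, so this was fixed in advance.

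Among single genes, the largest rises in deficient CD8 cells included Adam12, a metalloprotease with no count in floxed cells (at least 40.9-fold higher, adjusted p = 0.00544 by edgeR's quasi-likelihood test and 0.051 by limma voom), Klhl13 (at least 38.3-fold), the neuronal membrane protein Gpm6a (6.89 ± 1.33) and the copine Cpne4 (6.84 ± 0.80). After Mir155hg, the largest falls included the chaperone Clgn (-3.90 ± 0.91), the transcription factor Arnt2 (-3.88 ± 0.47), the calcium pump Atp2b2 (-3.75 ± 0.69), the matrix protein Npnt (-3.54 ± 0.52) and Tigit, an inhibitory receptor (-3.32 ± 0.50). Ifng, the cytokine interferon gamma, was at 753 ± 136 and 355 ± 159 CPM (-1.09 ± 0.41, adjusted p = 0.0852) and Tcf7, a transcription factor of memory cells, at 86.4 ± 76.5 and 234 ± 29.4 CPM (1.44 ± 0.48, adjusted p = 0.0501) by edgeR's quasi-likelihood test. Without floxed CD8 replicate 1, the Tcf7 value was 2.44 with an adjusted p of 0.000126, and by limma voom 2.09 with 0.000678. Tcf7 was also called with RLE scaling (0.0498), the stricter filter (0.0478), no filter (1.22e-16), DESeq2 (0.018), a fit of CD8 cells alone (0.0488) and the replicate block (0.0203). Ifng was called in a fit of CD8 cells alone (0.0193) and without a filter (1.57e-11). Without a filter edgeR's adjusted p thus fell from 0.0501 to 1.22e-16 for Tcf7 and from 0.0852 to 1.57e-11 for Ifng on the same counts. The cause of such drops was not tested, so values without a filter, here and below, are not taken as further support. In all, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 1359 genes higher and 1353 lower of 14080, with 3 libraries per group. The total of 2712 became 1641 without deficient CD8 replicate 1 and 115 with the melanoma and macrophage marker levels as covariates.

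**Figure D2:**
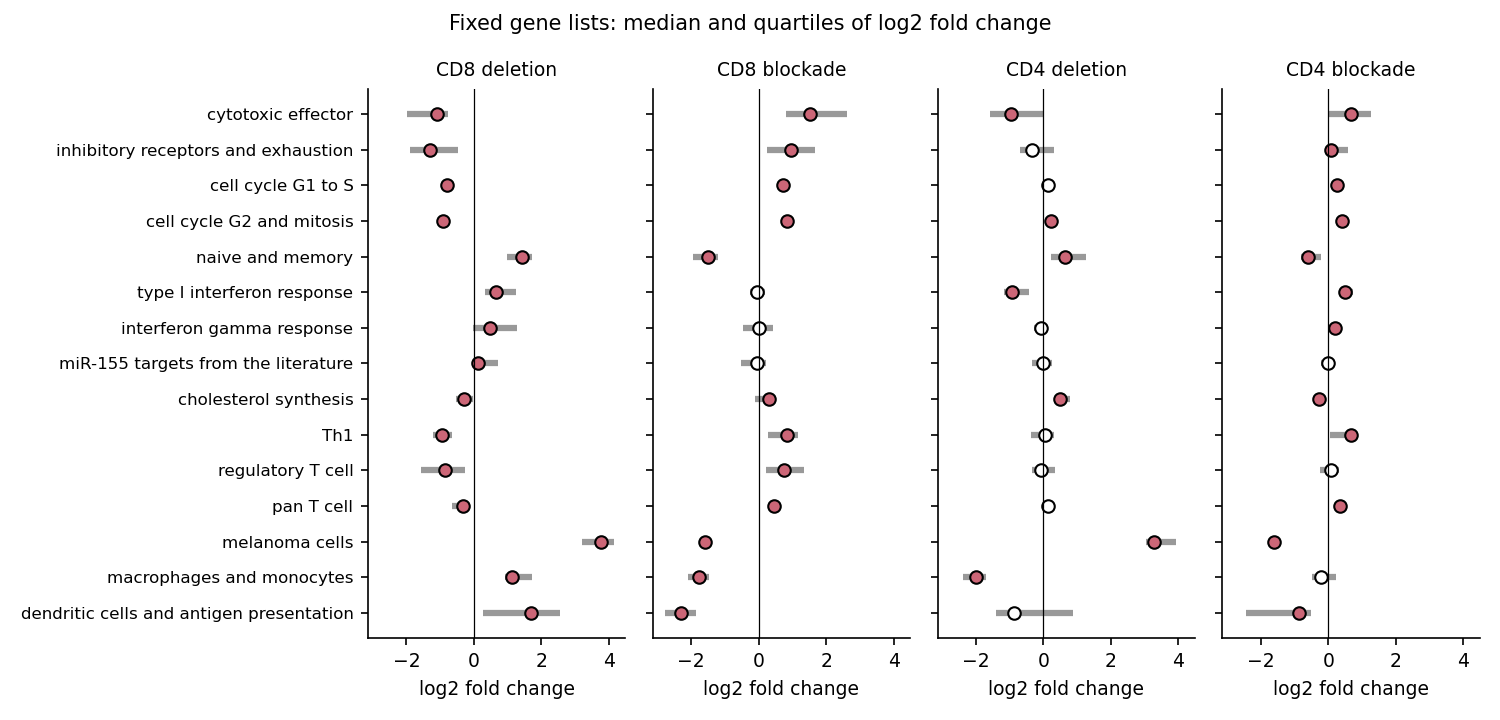
Log2 fold changes of 15 of the gene lists, in 1 panel per comparison. Points are list medians, bars span the quartiles and filled points are lists called by camera with the preset correlation. In CD8 cells the naive and memory, effector, exhaustion and cell cycle lists had opposite signs with the deletion and with the blockade.

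In CD4 cells the deletion went with lower macrophage, type I interferon and cytotoxic transcripts. Macrophage and monocyte genes such as Ctss (-1.72 ± 0.21) and Itgam (-1.98 ± 0.29) fell in 15 of 20 cases (19 adjusted over the list alone, median -2.00, camera adjusted p = 8.3e-21, adjusted p = 0.144 with an estimated correlation). Their sum was 19160 ± 7450 CPM in floxed, 4496 ± 952.3 in deficient and 4109 ± 975.5 in treated CD4 cells (SD, n = 3 each). Type I interferon response genes fell in 13 of 32 cases (20 adjusted over the list alone, median -0.94, camera adjusted p = 3.76e-12, adjusted p = 0.28 with an estimated correlation), with Ifit2 at -1.38 ± 0.20 and Oasl1 at -2.04 ± 0.32. Interferon gamma response genes had no call (1 up and 1 down of 35, median -0.07, camera adjusted p = 0.237). Cytotoxic effector genes fell in 10 of 25 cases (12 down and 1 up adjusted over the list alone, median -0.96, camera adjusted p = 8.47e-08, adjusted p = 0.144 with an estimated correlation), among them Nkg7 (-0.83 ± 0.11) and the chemokine Ccl3 (-1.77 ± 0.24). Cd8a fell by 8.77 and Cd8b1 by 2.54 on the log2 scale beside them, in the CD8 lineage list (3 of 6 down, 4 adjusted over the list alone, median -1.03, camera adjusted p = 0.00018, adjusted p = 0.144 with an estimated correlation). The 2 calls were lost with limma voom, at an adjusted p of 0.198 and 0.0917, and that of Cd8b1 also in a fit of CD4 cells alone (0.0692) and with the replicate number as a block (0.0532). With the melanoma and macrophage marker levels as covariates no camera call of these 4 lists held. The medians were then 0.077 (macrophage), 0.103 (type I interferon), -0.131 (cytotoxic) and -0.475 (CD8 lineage). For the macrophage list, which makes up a covariate, this loss was fixed in advance.

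Some metabolic lists were higher in deficient CD4 cells, while oxidative phosphorylation had no call (0 of 28 genes, median -0.05, camera adjusted p = 0.84). Cholesterol synthesis genes, with the enzymes Sqle (1.03 ± 0.15) and Msmo1 (0.97 ± 0.16), rose in 8 of 20 cases (14 adjusted over the list alone, median 0.50, camera adjusted p = 6.76e-08, adjusted p = 0.144 with an estimated correlation). Glycolysis genes such as Pdk1 (0.83 ± 0.16) rose in 6 of 21 cases (7 up and 1 down adjusted over the list alone, median 0.30, camera adjusted p = 0.000676, adjusted p = 0.366 with an estimated correlation). Hypoxia response genes rose in 3 and fell in 1 of 19 cases (8 and 1 adjusted over the list alone, median 0.47, camera adjusted p = 0.00018, adjusted p = 0.33 with an estimated correlation). Naive and memory genes, among them Gpr183 (0.85 ± 0.14) and S1pr1 (1.40 ± 0.28), rose in 4 of 18 cases (8 adjusted over the list alone, median 0.65, camera adjusted p = 7.55e-05, adjusted p = 0.33 with an estimated correlation). The immediate early genes Dusp1 (-1.40 ± 0.16) and Fos (-1.42 ± 0.17) led the dissociation stress list, where 7 of 20 fell (8 adjusted over the list alone, median -0.27, camera adjusted p = 1.93e-06, adjusted p = 0.178 with an estimated correlation). Genes of G2 and mitosis rose in 2 of 28 cases (2 adjusted over the list alone, median 0.23, camera adjusted p = 0.0077, adjusted p = 0.77 with an estimated correlation). That call was lost without floxed CD4 replicate 1 (adjusted p = 0.144) or 3 (0.319). With the covariates the medians were 0.256 (cholesterol), 0.003 (glycolysis), -0.202 (hypoxia), -0.410 (naive and memory) and -0.033 (G2 and mitosis), none of them called, while the dissociation stress list kept its call (median -0.448, adjusted p = 0.0053).

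Melanoma transcripts rose here too, 10 of 15 (13 adjusted over the list alone, median 3.27, camera adjusted p = 1.76e-10, adjusted p = 0.222 with an estimated correlation), and their sum was 344.4 ± 297.5 CPM in floxed, 3451 ± 1358 in deficient and 1062 ± 884.3 in treated CD4 cells. Natural killer cell genes fell in 4 of 11 cases (5 adjusted over the list alone, median -1.19, camera adjusted p = 0.0143, adjusted p = 0.144 with an estimated correlation). The miR-155 targets from the literature had no camera call (2 up and 5 down of 30, median -0.02, camera adjusted p = 0.312). The 1143 genes with seed sites gave a median difference of 0.05, by camera with a p of 0.262, and 1 of 353 controls was as large. With 3' UTR length matched, the difference of means was 0.042, and 68 of 353 controls were as large. Camera had no call for exhaustion (1 up and 7 down of 23, camera adjusted p = 0.0579), regulatory T cell (2 up and 3 down of 23) or Th1 genes (1 up and 2 down of 16). The exhaustion list was called in 6 of 13 alternative settings, the regulatory T cell and Th1 lists in 0 of 13.

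Among single genes the largest rise in deficient CD4 cells was in Gh, the gene of growth hormone (ENSMUSG00000020713, chromosome 11, 106300271 to 106301865, minus strand), at 36.2 ± 7.58 CPM against no count in floxed CD4 cells (at least 208-fold higher). Cpne4 (at least 45.0-fold), Gpm6a (at least 39.9-fold) and Slc44a3 (at least 47.0-fold) followed. Besides Cd8a, the largest falls included the macrophage genes Cd5l (no count in deficient cells, at least 128-fold lower), Retnla (-7.30 ± 1.28), Fcna (-6.27 ± 0.85), Spic (-5.50 ± 0.82) and Lyz1 (-5.41 ± 0.71), and Gzmf, a granzyme (-8.25 ± 2.18). The Gzmf call was lost with limma voom (0.526), without floxed CD4 replicate 2 (0.0628) or 3 (0.0868). It was lost too without deficient CD4 replicate 1 (0.119), 2 (0.101) or 3 (0.076). Ifng was at 158 ± 55.2 and 52.7 ± 18 CPM (-1.60 ± 0.44, adjusted p = 0.0305) and Havcr2 changed by -1.09 ± 0.28 (adjusted p = 0.0175) by edgeR's quasi-likelihood test. Both calls were lost with limma voom, at 0.16 and 0.0974, and that of Ifng in a fit of CD4 cells alone (0.0827). Both were lost without floxed CD4 replicate 2 (0.0888 and 0.0587), floxed CD4 replicate 3 (0.101 and 0.057) or deficient CD4 replicate 1 (0.133 and 0.0682). That of Ifng was lost also without deficient CD4 replicate 2 (0.101). Gzmb stood at 856 ± 80.3 and 843 ± 165 CPM, Prf1 at 176 ± 83.7 and 71.4 ± 9.30, and Pdcd1 at 286 ± 33.7 and 257 ± 23.5 CPM. Ctla4 stood at 1110 ± 326 and 1370 ± 58.9, and Foxp3, the regulatory T cell factor, at 49.3 ± 15.4 and 68.1 ± 10.4 CPM, and none of these genes was called. Prf1 was called lower with the replicate block (0.0237), with DESeq2 (0.0191), without a filter (5.4e-16) and without floxed CD4 replicate 1 (0.0178). In all, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 649 genes higher and 994 lower. The total of 1643 was 783 without floxed CD4 replicate 3, 818 without deficient CD4 replicate 1 and 4 with the marker levels as covariates.

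**Figure D3:**
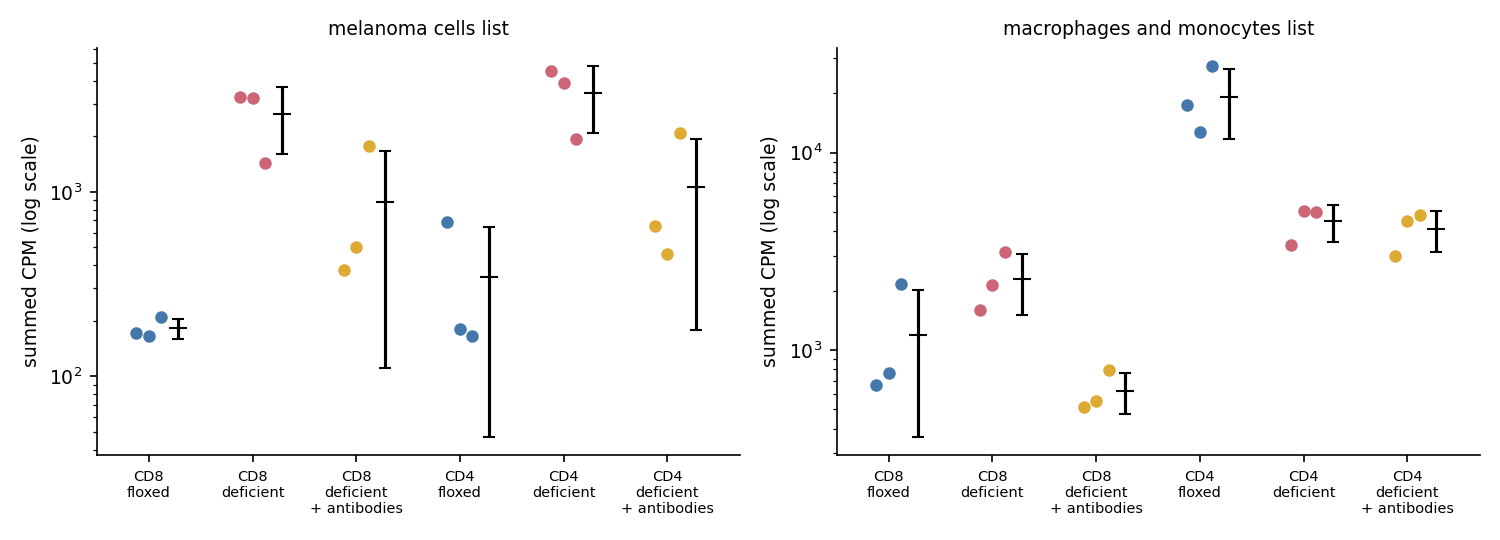
Summed CPM of the melanoma and the macrophage markers in each library, on a log axis, by group. Points are libraries and bars show the mean and SD of 3 libraries. Melanoma markers were highest in the untreated deficient groups, and macrophage markers were highest in floxed CD4 cells.

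The second question was what checkpoint antibodies do in deficient cells. In CD8 cells many lists that had moved with the deletion moved the other way, and 6 of them were also called with an estimated correlation. Cytotoxic effector genes rose in 18 and fell in 1 of 25 cases (19 and 1 adjusted over the list alone, median 1.52, camera adjusted p = 2.08e-22). Gzmb went from 754 ± 330 to 4670 ± 1080 CPM (2.63 ± 0.26), Prf1 from 325 ± 158 to 1420 ± 321 (2.13 ± 0.43) and Gzmk rose by 2.86 ± 0.26. Inhibitory receptor and exhaustion genes rose in 10 and fell in 2 of 23 cases (13 and 2 adjusted over the list alone, median 0.96, camera adjusted p = 9.31e-14), with Havcr2 at 2.68 ± 0.28, Entpd1 at 2.40 ± 0.18, Ctla4 at 1.67 ± 0.18 and Pdcd1 at 1.66 ± 0.15. Naive and memory genes fell in 14 of 18 cases (15 adjusted over the list alone, median -1.50, camera adjusted p = 1.28e-17), with Slamf6 at -1.28 ± 0.14. Genes of G1 to S rose in 24 of 27 cases (26 adjusted over the list alone, median 0.72, camera adjusted p = 8.08e-19). Regulatory T cell genes rose in 9 of 23 cases (11 up and 1 down adjusted over the list alone, median 0.75, camera adjusted p = 2.61e-08) and Th1 genes, led by Cxcr6 (2.19 ± 0.19), in 8 of 16 (9 adjusted over the list alone, median 0.84, camera adjusted p = 1.68e-07). In the order given, these 6 lists kept a call with an estimated correlation, at an adjusted p = 0.0124, 0.0296, 0.0338, 0.0449, 0.041 and 0.0449. With the marker levels as covariates they kept their calls with the preset correlation, at medians of 1.27, 0.52, -2.34, 0.54, 0.438 and 0.341.

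Other lists were called by camera with the preset correlation alone. Genes of G2 and mitosis rose in 23 of 28 cases (26 adjusted over the list alone, median 0.85, camera adjusted p = 7.51e-19, adjusted p = 0.106 with an estimated correlation). Glycolysis genes, with the glucose transporter Slc2a3 (1.75 ± 0.19) and Pfkp (0.88 ± 0.12), rose in 11 of 21 cases (13 up and 1 down adjusted over the list alone, median 0.47, camera adjusted p = 2.64e-07, adjusted p = 0.106 with an estimated correlation). Pan T cell genes rose in 5 of 12 cases (7 adjusted over the list alone, median 0.46, camera adjusted p = 1.91e-05, adjusted p = 0.215 with an estimated correlation). CD8 lineage genes were higher as a set (median 0.603, camera adjusted p = 0.00894). Genes induced by the T cell receptor rose in 5 of 24 cases (5 adjusted over the list alone, median 0.52, camera adjusted p = 0.00219, adjusted p = 0.317 with an estimated correlation). Macrophage genes fell in 17 of 20 cases (19 adjusted over the list alone, median -1.78, camera adjusted p = 2.01e-13, adjusted p = 0.106 with an estimated correlation). Antigen presentation genes fell in 9 with 1 rise of 14 (11 and 1 adjusted over the list alone, median -2.30, or -1.98 with groups at 0 set to the floor, camera adjusted p = 3.81e-07, adjusted p = 0.106 with an estimated correlation). No melanoma gene was called by edgeR's quasi-likelihood test, while camera called the list lower (median -1.58, adjusted p = 0.000992, adjusted p = 0.408 with an estimated correlation). Type I interferon response (1 up and 1 down of 32, median -0.06) and interferon gamma response genes (9 up and 8 down of 35, median -0.003) had no call. With the covariates the calls of the CD8 lineage (median 0.049), pan T cell (0.003), T cell receptor induced (-0.098), macrophage (0.102) and melanoma lists (0.054) were lost. For the macrophage and melanoma lists, which make up the covariates, this was fixed in advance. For the T cell lists that rose, less RNA of other cells was not told apart from an effect of the antibodies.

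The largest single rises were granzymes, Gzme (3.94 ± 0.68), Gzmd (3.83 ± 0.99) and Gzmf (3.74 ± 0.91), followed by Arnt2 (3.16 ± 0.48) and Filip1 (3.09 ± 0.41), with Klrg1, a receptor of effector cells, at 3.02 ± 0.29. Calls of Gzmd and Gzmf were lost without deficient CD8 replicate 1 (adjusted p = 0.0983 and 0.0727 by edgeR's quasi-likelihood test) or 3 (0.106 and 0.0755) or treated CD8 replicate 1 (0.0954 and 0.0638) or 2 (0.0768 and 0.0529). The largest falls included the serotonin receptor Htr1b (-4.09 ± 1.15), the transcription factor Zfhx4 (-3.69 ± 0.85) and the nucleotide receptor P2ry6 (-3.50 ± 0.66). The Htr1b call was lost with the replicate block (0.0531), without deficient CD8 replicate 1 (0.0593) or 3 (0.107) and without treated CD8 replicate 1 (0.0627), 2 (0.0861) or 3 (0.0901). Tcf7 changed by -1.97 ± 0.49 (adjusted p = 0.0171), a call lost without deficient CD8 replicate 1 (0.0559) or treated CD8 replicate 1 (0.0783) or 2 (0.0722). Ifng stood at 355 ± 159 and 785 ± 36.2 CPM (1.15 ± 0.42, adjusted p = 0.0877) by edgeR's quasi-likelihood test, against 0.00759 by limma voom, 0.0205 in a fit of CD8 cells alone and 7.52e-13 without a filter. Socs1 changed by -0.51 ± 0.15 (adjusted p = 0.0287). This call was lost without a filter (0.105) and without any library of these groups except treated CD8 replicate 2. The adjusted p was 0.0608, 0.0895 and 0.0775 without deficient CD8 replicates 1, 2 and 3 and 0.12 and 0.094 without treated CD8 replicates 1 and 3. In all, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 1162 genes higher and 779 lower. The total of 1941 was 1269 without deficient CD8 replicate 1 and 1192 without replicate 3. It was 919 without treated CD8 replicate 1, 1097 without replicate 2. It was 5139 with limma voom and 121 with the marker levels as covariates.

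**Figure D4:**
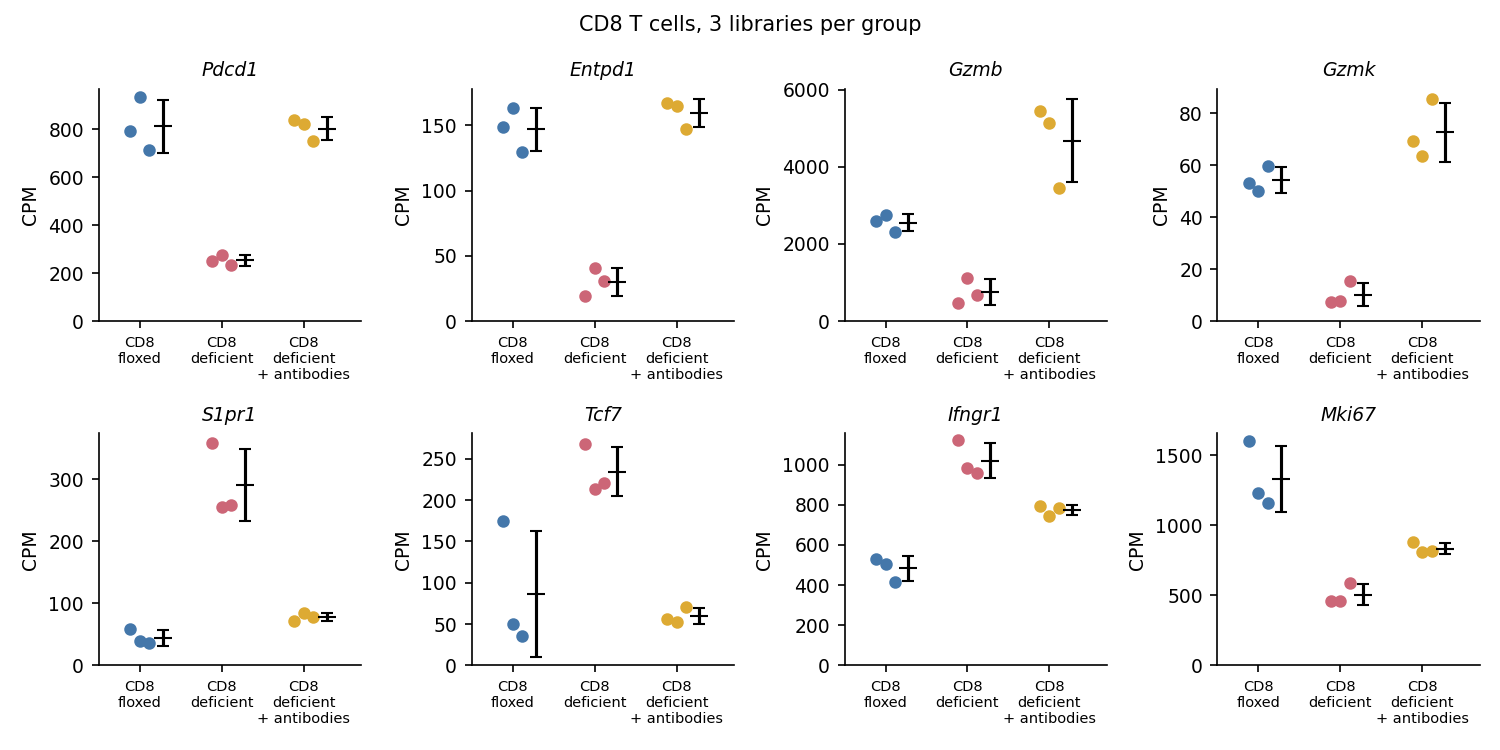
CPM of 8 genes in the 9 libraries of CD8 cells, by group. Points are libraries and bars show the mean and SD of 3 libraries. Pdcd1, Entpd1, Gzmb and Gzmk were lowest in untreated deficient cells, and S1pr1 was highest there.

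In CD4 cells 20 genes passed the test of the blockade, against 1590 at an unadjusted p under 0.05. Cxcr6 rose by 1.17 ± 0.18, Pdcd1 from 257 ± 23.5 to 431 ± 91 CPM (0.75 ± 0.14) and Themis, a T cell signalling protein, by 0.94 ± 0.17. The macrophage genes Fcna (5.54 ± 0.85) and Folr2 (2.68 ± 0.39) rose with them. The macrophage list as a whole was not called by camera (adjusted p = 0.459, and in 0 of 13 alternative settings). Its sum was 4496 ± 952.3 CPM in deficient and 4109 ± 975.5 in treated CD4 cells. Il10, a cytokine that damps immune responses, fell from 175 ± 18 to 57.8 ± 19 CPM (-1.58 ± 0.28), and Flt3, a receptor of dendritic cells, by 2.57 and Kmo, an enzyme of tryptophan breakdown, by 2.28 on the log2 scale. Each of these calls was lost without at least 1 library, that of Il10 also with the replicate block (0.0713) and those of Pdcd1 (0.0875) and Themis (0.0515) in a fit of CD4 cells alone. Gzmb was at 843 ± 165 and 849 ± 131 CPM and Foxp3 at 68.1 ± 10.4 and 66.4 ± 5.96 CPM. EdgeR's quasi-likelihood test called 12 genes higher and 8 lower, DESeq2 177 and limma voom 315. The 20 became 0 without deficient CD4 replicate 1, 12 without replicate 2, 9 without replicate 3, 0 without treated CD4 replicate 1, 2 without replicate 2 and 106 without replicate 3.

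Camera called 20 of the 35 lists for the CD4 blockade, and 0 with an estimated correlation. Type I interferon response genes were higher as a set (0 of 32 called, 10 up adjusted over the list alone, median 0.50, camera adjusted p = 2.93e-14, adjusted p = 0.185 with an estimated correlation). So were genes of G2 and mitosis (0 of 28, 1 up adjusted over the list alone, median 0.42, camera adjusted p = 1.37e-10, adjusted p = 0.225 with an estimated correlation). So were cytotoxic effector genes (0 of 25, 10 up and 1 down adjusted over the list alone, median 0.67, camera adjusted p = 1.39e-07, adjusted p = 0.144 with an estimated correlation). CD8 lineage genes were higher beside them (0 of 6 called, 2 up adjusted over the list alone, median 0.39, camera adjusted p = 0.00325, adjusted p = 0.185 with an estimated correlation). Cd8a stood at 0.226 and 8.09 CPM (adjusted p = 0.304 by edgeR's quasi-likelihood test, 0.0115 with the replicate block, 0.000519 with DESeq2 and 3.12e-24 without a filter). Th1 genes (1 of 16 up, 7 adjusted over the list alone, median 0.66) had a camera adjusted p = 1.55e-06, and an adjusted p = 0.115 with an estimated correlation. Antigen presentation genes were lower (1 of 14 down, 6 adjusted over the list alone, median -0.88, camera adjusted p = 3.07e-08, adjusted p = 0.115 with an estimated correlation). Melanoma genes were lower too (0 of 15 called, 0 adjusted over the list alone, median -1.62, camera adjusted p = 2.7e-07, adjusted p = 0.225 with an estimated correlation). With the covariates the CD8 lineage list lost its call (median 0.135, camera adjusted p = 0.424). The cytotoxic (0.236) and Th1 lists (0.309) kept theirs with smaller medians. Those of type I interferon (0.476), G2 and mitosis (0.4) and antigen presentation genes (-1.153) held.

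The last question was how far treated deficient cells still differ from untreated floxed cells. In CD8 cells none of the fixed effector and receptor genes passed the test, with Gzmb at 4670 ± 1080 against 2560 ± 229 CPM (0.87 ± 0.25, adjusted p = 0.0531) and Prf1 at 0.10 ± 0.41 (adjusted p = 0.929) by edgeR's quasi-likelihood test. Camera called the cytotoxic effector list higher (3 of 25 up, 4 up and 1 down adjusted over the list alone, median 0.43, adjusted p = 0.0321, adjusted p = 0.635 with an estimated correlation). That call was lost without floxed CD8 replicate 2 (0.0877) or 3 (0.0551) and without treated CD8 replicate 1 (0.0799) or 2 (0.0531). By edgeR's quasi-likelihood test, Ifng was at 0.06 ± 0.41 (adjusted p = 0.959), Pdcd1 at -0.02 ± 0.14 (adjusted p = 0.963) and Havcr2 at 0.00 ± 0.26 (adjusted p = 0.997). Gzmb was called with DESeq2 (0.00738), with the stricter filter and with the replicate block (0.0498 each), without a filter (5.37e-08) and without treated CD8 replicate 3 (0.0432). Genes of the interferon gamma response were higher, 15 of 35 (22 adjusted over the list alone, median 0.47, camera adjusted p = 5.22e-13, adjusted p = 0.307 with an estimated correlation). Genes of the type I interferon response were higher too, 12 of 32 (16 adjusted over the list alone, median 0.58, camera adjusted p = 2.89e-12, adjusted p = 0.337 with an estimated correlation). Melanoma genes were higher as a set beside them (0 of 15 called, 0 adjusted over the list alone, median 2.225, camera adjusted p = 0.000135, adjusted p = 0.487 with an estimated correlation). So were reported miR-155 targets (5 up and 2 down of 30, 8 and 3 adjusted over the list alone, median 0.215, camera adjusted p = 0.0106, adjusted p = 0.307 with an estimated correlation). The target call was lost without floxed CD8 replicate 2 (0.146) or 3 (0.0551). Besides Mir155hg (-5.20 ± 0.73), the ribosomal protein gene Rpl29 (-3.45 ± 0.45) was lower, and Stc2, a secreted glycoprotein, was higher (2.97 ± 0.39). In all 379 genes were higher and 327 lower, a total of 706. It was 261 without floxed CD8 replicate 1, 1503 without replicate 2, and 141, 111 and 247 without treated CD8 replicates 1, 2 and 3. The total was 1385 with DESeq2, 439 in a fit of CD8 cells alone, 58 without the 3 libraries rich in ribosomal-like counts and 171 with the marker levels as covariates.

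In treated CD4 cells macrophage genes were lower than in floxed cells, 18 of 20 (19 adjusted over the list alone, median -2.24, camera adjusted p = 1.61e-22, adjusted p = 0.191 with an estimated correlation). Genes of G2 and mitosis were higher, 14 of 28 (21 adjusted over the list alone, median 0.63, camera adjusted p = 1.52e-12, adjusted p = 0.243 with an estimated correlation). Glycolysis genes were higher too, 10 of 21 (11 adjusted over the list alone, median 0.43, camera adjusted p = 1.03e-05, adjusted p = 0.243 with an estimated correlation). Melanoma genes were higher as a set beside them (median 1.711, camera adjusted p = 0.00171). With the covariates the glycolysis call was lost (median 0.177, camera adjusted p = 0.192), while G2 and mitosis kept theirs with a smaller median (0.349). Gh (at least 228-fold higher) and Stc2 (4.51 ± 0.45) led the rises, and after Mir155hg (-5.63 ± 0.83) the endothelial lipase gene Lipg (-4.43 ± 0.83) led the falls. Pdcd1 was higher (0.59 ± 0.14, adjusted p = 0.00933 by edgeR's quasi-likelihood test), a call lost without floxed CD4 replicate 3 (0.0648) or treated CD4 replicate 2 (0.0668). In all 575 genes were higher and 1137 lower. The total of 1712 was 782 without floxed CD4 replicate 3, 923 without treated CD4 replicate 1 and 6 with the marker levels as covariates.

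Across the 14080 genes, which are not independent replicates, deletion and blockade effects in CD8 cells ran in opposite directions (Pearson's r = -0.604, covariance -0.559). Simulations with no effect gave r = -0.489 (-0.522 to -0.468) and a covariance of -0.121, because the untreated deficient libraries enter both, and the covariances differed by -0.438. Of 1359 genes higher with the deletion, 407 were called lower with the blockade (75.2 for independent lists), and of 1353 lower ones 713 were called higher (111.7 for independent lists). Of the deletion calls, 309 stood with the same sign in treated deficient against floxed CD8 cells (184 higher and 125 lower, against 36.6 and 31.4 for independent lists). The 309 were 126 without floxed CD8 replicate 1, 735 without replicate 2, 200 and 203 without deficient CD8 replicates 1 and 2, and 96, 79 and 115 without treated CD8 replicates 1, 2 and 3. In CD4 cells r was -0.517 against a simulated -0.507 (-0.538 to -0.48) and the covariance -0.45 against -0.124. There 939 of the 1643 deletion calls stood with the same sign (204 higher and 735 lower, against 26.5 and 80.3 for independent lists), and 425 without floxed CD4 replicate 3 or 579 without deficient CD4 replicate 1. With 3 libraries per group no split of the shared group left 2 in each part, so part of each excess may come from the shared libraries. The simulations also held no RNA of other cells. In CD8 cells summed melanoma and macrophage markers were highest in the shared untreated deficient group, at 2651 and 2290 CPM. They were at 181.8 and 1194 in floxed and at 887 and 620.8 in treated cells. How much of the relation came from such RNA was not tested.

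**Figure D5:**
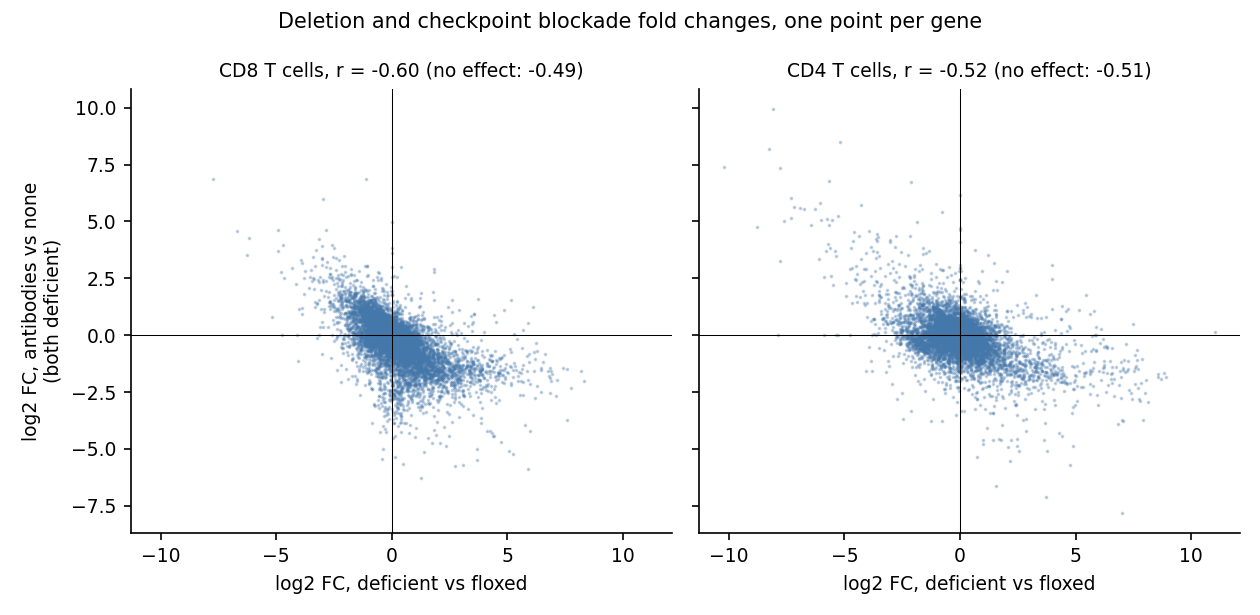
Log2 fold change with the deletion (x axis) against that with the blockade (y axis) for each tested gene, in CD8 and CD4 cells. The cloud slopes downward in both, with r of -0.604 and -0.517, and part of the slope comes from the libraries that both comparisons share.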

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

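The tests of dilution, of the macrophage quartile, of the CD8 share, of Gh, of the chromosome 9 window, of ribosomal-like counts and of the covariates were chosen after the result was seen, and that of regrouped libraries before.

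The deletion differed between CD8 and CD4 cells in 1634 genes, 970 with a higher and 664 with a lower effect in CD8 cells by edgeR's quasi-likelihood test. With the melanoma and macrophage marker levels as covariates the 1634 were 25. Values here are the log2 change in CD8 minus that in CD4 cells, and each result stands here because of this difference between groups. The effect on inhibitory receptors was lower in CD8 cells, with Pdcd1 at -1.52, Ctla4 at -1.60 and Havcr2 at -1.59. So was that on Gzmb (-1.74), and the effect on Socs1, the cytokine brake, was higher (0.69). The cytotoxic list had no call (camera adjusted p = 0.0905), but was called in 6 of 18 alternative settings. The largest positive differences were Fam71a (10.07), the macrophage transcription factor Spic (9.75), Klra13-ps (9.49), Cd8a (7.84), the growth factor Pdgfc (7.76), Ltc4s (7.33), the iron exporter Slc40a1 (7.15), B3galnt1 (7.07), Rgs18 (7.03) and the endothelin receptor Ednrb (6.96). The largest negative ones included Rassf6 (-7.28), the adhesion protein Nectin3 (-7.26), Arnt2 (-4.46), Grb7 (-3.84), Il17rc (-3.82), the chemokine receptor Ccr3 (-3.73), Pak6 (-3.71), the hypoxia factor Epas1 (-3.37) and Plcxd1 (-3.18). Of 25 called named genes, 19 kept the call without each library in turn, and 2 lost it with the replicate block.

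List medians of the same difference were positive for type I interferon (1.54), interferon gamma (0.61), naive and memory (0.70), follicular helper (0.90), miR-155 target (0.27) and dissociation stress genes (0.42). They were positive as well for macrophage (2.95), antigen presentation (2.97), natural killer (2.33) and gamma delta T cell genes (2.02). They were negative for genes of G2 and mitosis (-1.17), G1 to S (-0.80), regulatory T cells (-0.97), Th1 (-0.94), exhaustion (-0.92), cholesterol synthesis (-0.81), T cell receptor induction (-0.64), pan T cell (-0.59) and glycolysis (-0.46). Of these 19 lists the natural killer list alone kept a camera call with an estimated correlation (adjusted p = 0.0326), and its call was lost with the covariates (median 1.384, adjusted p = 0.0749).

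The blockade differed between the cell types in 113 genes, 81 with a higher and 32 with a lower effect in CD8 cells by edgeR's quasi-likelihood test. The 113 were 61, 75 and 71 without deficient CD8 replicates 1, 2 and 3, and 49 and 56 without treated CD8 replicates 1 and 2. They were 58 without deficient CD4 replicate 2 or 3, and 65 and 73 without treated CD4 replicates 1 and 3. They were 286 with the replicate block, 355 with DESeq2, 818 with limma voom, 665 without a filter, 63 with the covariates and 50 without the 3 libraries rich in ribosomal-like counts. Genes higher in CD8 included Rassf6 (6.21), the cytokine Il10 (3.73), Arnt2 (3.51), Klrg1 (3.26), the receptor Cd244a (2.66), Ifitm1 (2.64), Gzmb (2.62), Entpd1 (2.42), Ccl4 (2.22), Havcr2 (2.02), Ctla4 (1.94) and Pdcd1 (0.92). Lower were Klra13-ps (-6.76), the macrophage genes Fcna (-6.59), Folr2 (-3.98) and Mertk (-3.17), Abca9 (-4.88), the sialyltransferase St6gal1 (-2.54), Tnfsf8 (-2.50), the interleukin 6 receptor Il6ra (-2.23), Fgd6 (-2.02) and Mcoln2 (-2.02). Of 23 called named genes, 12 kept the call without each library in turn, and 1 lost it with the replicate block. List medians were positive for cytotoxic (0.78), regulatory T cell (0.63), G2 and mitosis (0.49), cholesterol (0.48), G1 to S (0.46), glycolysis (0.40), exhaustion (0.39), oxidative phosphorylation (0.33) and Th1 genes (0.20). They were negative for macrophage (-1.52), follicular helper (-1.03), naive and memory (-0.93), Th17 (-0.93), antigen presentation (-0.93), type I interferon (-0.63), interferon gamma (-0.30) and miR-155 target genes (-0.21). None of these 17 lists kept a camera call with an estimated correlation.

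In deficient CD8 cells naive and memory transcripts were higher and effector, exhaustion and cell cycle transcripts lower. Dilution by RNA of melanoma cells or macrophages would lower all T cell lists, and the lower quartile of the naive and memory list was 0.97 (18 genes), which argues against it for that list. For the lists that fell, dilution and the deletion cannot be told apart. The lower quartile of the pan T cell list was -0.65 (12 genes), a smaller fall than the smallest of the 4 list medians (-0.79), while the CD8 lineage median of -0.85 was as low. Without the libraries rich in ribosomal-like counts the 5 list medians kept 0.89 to 1.28 of their size. Of these libraries only floxed CD8 replicate 1 enters the CD8 deletion, so the result argues only against that library as the cause. With melanoma and macrophage marker levels as covariates the ratios ran from 0.47 to 1.21, with the cytotoxic median at -0.51 instead of -1.09. An effect of these marker levels and of the deletion on the cytotoxic list cannot be told apart, because the levels follow the groups, and the loss of miR-155 itself stays open beside it.

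In deficient CD4 cells macrophage and cytotoxic transcripts were lower. The upper quartile of the macrophage list was -1.71 (20 genes), which only restates the fall, so less carried-over macrophage RNA and a change through the deletion cannot be told apart. With both marker levels as covariates, the 1618 other called genes kept a median of 0.3 of their log2 fold change (quartiles -0.09 and 0.71). Because these levels follow the groups (R squared 0.81 and 0.9), such a loss is expected whatever the cause, and RNA of other cells and the deletion cannot be told apart for these genes. CD8 T cells among the floxed CD4 cells would give a median of 36.2% of the fall of 10 called cytotoxic genes (2.4% to 105%). They would give at least 50% for 3 genes, Gzmf (105%), Gzmk (60.8%) and Ifng (58.1%). For Lamp1 (2.4%), Zeb2 (3.1%) and Tnf (14.1%) they would leave most of the fall unexplained. For the 10 genes as a set CD8 cells and the deletion cannot be told apart, because the cover differed by gene and the share came from only 2 genes. A biological change in the tumor's cells through the loss of miR-155 was not tested apart from these.

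Some genes differed in the Cre libraries of both cell types, 24 higher and 13 lower in all 4 comparisons with floxed cells. Gh, which is not among these 37 genes, was at 31.4 CPM or more in each of 6 CD4 Cre libraries (mean 37.9 ± 6.2). It was at 0 in the 6 floxed libraries and at most 1.66 in CD8 Cre libraries, which could come from a growth hormone cassette in the transgene. The first bound, at most 3 counts of 6 other pituitary genes in the CD4 Cre libraries, was not met (49 counts in 6 libraries, against 10 in the 3 floxed CD4 libraries), and it was replaced after that result by a rise under 1 CPM, where 0.54 was seen. Of the 37 genes, 5 lay within 10 Mb of each other on chromosome 9, which 2000 permutations gave a p of 0.005, so a linked stretch of chromosome could account for these 5. No biological explanation was tested for them. Summed melanoma markers were also higher in untreated and treated Cre groups, at 2651 and 887 against 181.8 CPM in CD8 cells. In CD4 cells they were at 3451 and 1062 against 344.4 CPM. Whether melanoma RNA gave part of the 24 rises, Cpne4 on chromosome 9 among them, was not tested.

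Regrouped libraries gave 10 splits within each pair of groups, too few for a share under 0.05. The real split called the most genes in each, as 1 of 10, with 2712 against at most 9 for the CD8 deletion, 1643 against 0 for the CD4 deletion, 1941 against 0 for the CD8 blockade and 20 against 0 for the CD4 blockade. The further values were 706 against 0 and 1712 against 8 for treated CD8 and CD4 cells against floxed, and 5506 against 1 for CD8 against CD4 cells. For the difference of the deletion between cell types, 1 of 40 splits, the real one, reached 1634 genes (highest other 1318). Regrouping within each cell type removes the deletion effect itself, not only its difference between cell types. It therefore cannot tell whether that difference arose by chance. Of the other splits, 11 kept the real split in 1 cell type and so held its effect, the 1318 among them, and the highest without those was 0. For the difference of the blockade 3 of 40 splits reached 113 genes (highest other 583). The same limit holds here, and chance is not excluded by this share. Of the other splits, 5 kept the real split in 1 cell type and so held its effect, the 583 among them, and the highest without those was 1.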

How the results depend on the processing

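The covariates for melanoma and macrophage marker levels and the fits without 3 libraries rich in ribosomal-like counts were chosen after the result was seen, and the other alternatives before. No called named gene and no called list changed direction when 1 library was left out. RLE scaling kept 411 of 415 gene results and 161 of 162 list results, the stricter filter 406 of 408 genes, DESeq2 403 of 413, no filter 384 of 415, limma voom 349 of 415 and the fits of 1 cell type 302 of 334. Of 162 list calls, fry kept 129 and camera with an estimated correlation 19. Leaving out 1 library kept 2361 of 2886 gene results and 1115 of 1188 list results, with 3 libraries per group and fewer when 1 is left out. For the changes below the cause was not tested.

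Counts of called genes changed as follows. With the covariates they were 115 (CD8 deletion), 4 (CD4 deletion), 121 (CD8 blockade), 5 (CD4 blockade), 171 and 6 (treated CD8 and CD4 against floxed), 25 (difference of the deletion between cell types) and 63 (that of the blockade). Limma voom gave 5139 (CD8 blockade), 315 (CD4 blockade) and 818 (difference of the blockade). DESeq2 gave 177 (CD4 blockade), 1385 (treated CD8) and 355 (difference of the blockade), and no filter 541, 1574 and 665 for the same. Without the 3 libraries they were 4, 58 and 50 for the same. A fit of CD8 cells alone gave 439 for treated CD8, and a fit of the floxed libraries alone gave 3454 for CD8 against CD4. Leaving out 1 library gave 1641 to 2716 (CD8 deletion), 783 to 1584 (CD4 deletion), 919 to 1651 (CD8 blockade), 0 to 106 (CD4 blockade), 111 to 1503 (treated CD8), 782 to 1999 (treated CD4) and 49 to 108 (difference of the blockade).

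The seed difference in the CD8 deletion was 0.09 for 8mer sites (camera p = 0.0829), 0.108 with an estimated correlation (p = 0.0868) and 0.076 to 0.127 when 1 library was left out. The correlation of deletion and blockade was -0.699 in CD8 and -0.414 in CD4 cells for genes above the median expression, and -0.637 to -0.465 and -0.584 to -0.438 when 1 library was left out. Deletion calls kept in treated cells were 622 for CD4 genes above the median, and 79 to 735 (CD8) and 425 to 1067 (CD4) when 1 library was left out.

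Some genes changed direction. With the covariates these were 14 of 69 called named genes in the CD4 deletion, where 0 kept the call, 2 of 25 in treated CD4, and 1 of 74 each in the CD8 deletion and the CD8 blockade. With DESeq2 these were Havcr2 in treated CD8 against floxed (-0.02) and Cd8b1 in the difference of the blockade (-0.10), and with RLE scaling Havcr2 in treated CD8 (-0.02). With limma voom they were Inpp5d (0.10) and Cd4 (0.54) in the CD8 deletion, Ifng (-0.02), Havcr2 (0.00) and Tcf7 (0.08) in treated CD8, Gzmb in treated CD4 (0.01), and Ifng (0.08) and Cd4 (0.09) in the difference of the blockade. Gzmb in treated CD4 was 0.02 without a filter and 0.00 in a fit of CD4 cells alone. When 1 library was left out, values ran from -0.25 to 0.19 for Inpp5d and -0.71 to 0.56 for Cd4 in the CD8 deletion, -0.19 to 0.09 for Gzmb in the CD4 deletion, -3.09 to 5.03 for Foxp3 in the CD8 blockade, and -0.11 to 0.18 for Gzmb and -0.10 to 0.12 for Foxp3 in the CD4 blockade. In treated CD8 they ran from -0.10 to 0.34 for Inpp5d, -0.04 to 0.21 for Ifng, -0.05 to 0.28 for Prf1, -0.11 to 0.10 for Pdcd1, -0.11 to 0.18 for Havcr2, -0.90 to 0.50 for Tcf7, -5.34 to 0.54 for Foxp3 and -0.13 to 1.12 for Cd4. In treated CD4 they ran from -0.01 to 0.07 for Inpp5d, -0.57 to 0.10 for Ifng, -0.10 to 0.11 for Gzmb, -0.16 to 0.25 for Ctla4 and -0.08 to 0.40 for Tcf7. In the difference of the deletion Mir155hg ran from -0.76 to 0.91. In that of the blockade they ran from -0.60 to 0.11 for Ifng, -3.06 to 5.05 for Foxp3, -0.47 to 1.21 for Mir155hg, -0.42 to 0.36 for Cd4 and -0.48 to 0.54 for Cd8b1.

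Lists whose camera direction changed with the covariates, given with their medians there, were CD8 lineage (0.491), melanoma (0.182) and macrophage genes (-0.281) in the CD8 deletion, and naive and memory (-0.410), type I interferon (0.103), hypoxia (-0.202), macrophage (0.077) and natural killer genes (0.040) in the CD4 deletion. In the CD8 blockade they were melanoma (0.054) and macrophage genes (0.102), and in the CD4 blockade T cell receptor (-0.090) and melanoma genes (-0.079). In treated CD4 they were pan T cell (-0.273), hypoxia (-0.063), macrophage (0.103) and antigen presentation genes (0.063). For the difference of the deletion they were pan T cell (0.353), macrophage (-0.136) and antigen presentation genes (0.130), and for that of the blockade macrophage (0.303) and antigen presentation genes (0.162). The medians of endothelial genes in the CD8 deletion (-0.272), G2 and mitosis in the CD4 deletion (-0.033) and T cell receptor genes in the CD8 blockade (-0.098) also changed sign. Oxidative phosphorylation in treated CD8 was 0.010 without the 3 libraries. The covariates follow the groups (R squared 0.96 and 0.74 in CD8, 0.81 and 0.9 in CD4 cells for melanoma and macrophage levels), so they also remove group effects. They are made from the melanoma and macrophage lists, so the changes of those lists with the covariates were fixed in advance.

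The libraries share replicate numbers, which the labels do not explain. With the number as a replicate block, 58 genes were called for the CD4 blockade, 286 for the difference of the blockade, and Mir155hg in the difference of the deletion was -0.14. The block kept 387 of 415 gene results and 158 of 162 list results. Within a cell type 2 of 18 pairs with the same number correlated over 0.1 (-0.182 to 0.184), and across cell types 5 of 9 (0.003 to 0.289), where 8 of 9 correlated best with their own number, a hint from the data and not from the design.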

Other observations

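No test in this part was chosen after the result was seen, and the values come from the comparison of floxed cells and from group sums. Between floxed CD8 and CD4 cells camera called 22 of 35 lists, 6 higher and 16 lower in CD8 cells. With an estimated correlation 9 were called. The lists given here are a selection from the 22 that was not fixed in advance.

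Floxed CD8 and CD4 cells differed in the cell cycle and in interferon genes. All 28 genes of G2 and mitosis and 26 of 27 of G1 to S were higher in CD8 cells (medians 1.40 and 1.18, camera adjusted p = 8.22e-21 and 1.71e-21). With an estimated correlation they had an adjusted p = 0.0575 and 0.0226. Type I interferon response genes were lower in CD8 cells, 31 of 32 (median -1.92, camera adjusted p = 1.49e-22, adjusted p = 0.0575 with an estimated correlation). Reported miR-155 targets were lower in CD8 cells as well, 18 of 30 with 1 higher (median -0.69, camera adjusted p = 9.1e-10, adjusted p = 0.0127 with an estimated correlation), beside Mir155hg at 16.3 ± 6.26 CPM in CD8 and 6.61 ± 1.68 CPM in CD4 cells. The Mir155hg difference was not called by edgeR's quasi-likelihood test (adjusted p = 0.0702), but was with DESeq2 (0.0457), with limma voom (0.0148), in a fit of the floxed libraries alone (0.0351) and without floxed CD8 replicate 3 (0.0403). Macrophage genes were lower in CD8 cells, 18 of 20 (median -4.15, camera adjusted p = 1.64e-22, adjusted p = 0.0363 with an estimated correlation).

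Summed over the list, cytotoxic effector transcripts stood at 9919 ± 842.2 CPM in floxed, 4038 ± 975.9 in deficient and 14180 ± 2882 in treated CD8 cells (SD, n = 3 each). Naive and memory transcripts stood at 1012 ± 449.7, 3179 ± 461.9 and 1134 ± 48 CPM in the same groups. The antibody effect in floxed mice was not analysed here, so whether it differs with miR-155 was not tested.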
